A study of Homo sapiens with 3 samples.

How the data were processed

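Total RNA from asynchronously growing HUH7 cells, a human hepatocellular carcinoma line, was measured on 3 Affymetrix Human Gene 1.0 ST arrays, a whole-transcript platform that carries several short probesets along each gene. Per the labels, the RNA came from different plates of the same line, with no treatment and no other group, so the design holds 1 group of 3 samples and no contrast between conditions. Any spread between arrays is the spread between these plates together with the technical error of labelling and hybridisation.

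The deposited values are on a log2 scale: they ran from 3.95 to 15.73, the range that log2 of scanner brightness gives, and no label states the base of the logarithm. Per the submitters' processing notes, Partek and GCRMA, a background correction that uses probe sequence, were used. Versions, the step between arrays and the summary method are not given in the sources used here. The table holds 257101 probesets, which lie below the gene level, with no missing value. The median of the deposited log2 values was 8.72 on array 1, 8.28 on array 2 and 8.45 on array 3, so the arrays do not share a common distribution. Exactly equal values in 2 arrays occurred in 2372 to 5456 probesets depending on the pair, and no 2 arrays held the same data.

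Gene names were taken from the platform annotation. It gave 1 symbol for 224320 probesets, several for 10159 and none for 22622, and only probesets with 1 symbol were used for genes. Of the distinct symbols, 16068 were current in the RefSeq gene table of GRCh38.p14, 2533 were updated through a synonym carried by a single gene, and 100 were kept as given. XIST and Y-linked genes were left out. This left 18622 genes with a median of 10 probesets each, 1041 of them with 1 probeset. A gene's level on an array was the median of its probesets. The arrays' precision is limited by their number, and levels of different genes depend on how well their probes bind, so no gene was ranked against another by a test.

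A background was set on each array as the 95th percentile of 348 olfactory receptor genes, a family not expected in liver cells, which gave thresholds of 6.81, 6.56 and 6.85 on arrays 1, 2 and 3. Only 476 probesets covered these 348 genes, against a median of 10 per gene, so the threshold also carries the spread of single probesets. Genes of few and of many probesets were held to the same threshold. These genes were then left out, and the other 18274 were each tested for a level above the threshold with limma (version 3.58.1, R 4.3.3), in a one-sample fit with moderated variance and a one-sided p adjusted by Benjamini and Hochberg over all genes tested. An adjusted p under 0.05 is called "above background". The moderation estimated an infinite number of prior degrees of freedom, so every gene was given the same SD of 0.188 in this test, and a gene with an unusually wide spread between plates was tested against too small an error. Fits without moderation and with robust moderation were therefore set beside it. The threshold is itself an estimate shared by all genes, and its error is not in the p-values. On simulated arrays with the real means and SDs of the 18274 genes, 70% of 50 genes placed 0.25 log2 units above the threshold were called and 100% of those placed 0.5 units above, while 3.35% of 2000 genes placed exactly at it were called.

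There were 26 gene lists with 650 entries fixed before the data were examined, as were the main test, the alternatives and the rule for named genes. The 610 genes measured among them were counted as above background or not, and each list was compared with all other tested genes by Fisher's exact test, two-sided, adjusted by Benjamini and Hochberg over the 26 lists (scipy 1.17.1). Genes are not independent replicates, so these p-values describe the lists on these arrays. Adjusted over the list alone, every list had the same count. Members without a probeset of their own are not analysed here. Movement of a list between plates was measured as the highest minus the lowest array median of its members' deviations from their own means, and compared with 10000 random lists of the same size matched on level in 20 bins. On arrays centred on their median gene, with shuffled gene names, this called 0 of 26 lists. A rise of 0.3 log2 units planted on array 1 in the list of DNA replication genes was called there. The arrays as deposited, which carry the shift of the whole array, were not checked in this way.

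The genes named are a panel of 30 fixed in advance (27 measured), the 2 highest members above background and the 2 lowest not above it in each list, the 10 genes of highest level with at least 4 probesets, and the 10 genes above background with the widest difference between plates. Where 5 or fewer members of a list stood on one side of the threshold, those outside the rule were named as well, after their values were seen. So were PCK2 and all members not above background in the list of gluconeogenesis and glucose handling. Alternatives covered the percentile and the family that set the background, the summary over probesets, filters on probesets, quantile normalization, a margin of 0.5 log2 units, the variance model and leaving out each array in turn. Centring of the arrays, robust moderation and 6 further gene lists were added after the first results were seen.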

Results

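Gene expression was profiled in HUH7 cells, a hepatocellular carcinoma line widely used as a model of human liver cells, while they cycled asynchronously. The series holds 3 arrays, each from a different plate, in a single group. The labels state no comparison between conditions, so the question addressed here is which genes these cycling cells expressed above background and how far the plates agreed. Values below are log2 units above the background threshold of each array, as mean ± SD over the 3 plates (n = 3), unless stated otherwise. Across genes, the arrays correlated with Pearson's r of 0.9961 to 0.9965 and Spearman's rho of 0.9937 to 0.9944 for the 3 pairs (genes are not independent replicates, so no p is given). The median SD of a gene over the plates was 0.203 as deposited and 0.157 after subtraction of the array's threshold.

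Genes of liver plasma proteins, cell division, sterol synthesis and fatty acid synthesis were above background in HUH7 cells more often than other genes, while several enzymes and transporters of mature hepatocytes, most endothelial, leukocyte and neuronal markers and most interferon stimulated genes were not above background. Of 18274 genes tested, 12024 (65.8%) were above background by limma, 4991 were below the threshold and 1259 were on neither side. In the fixed panel, 22 of 27 measured genes were above background. The 5 that were not were CYP7A1, the rate-limiting enzyme of bile acid synthesis, at -1.63 ± 0.10, CYP3A4 and CYP2E1, drug-metabolising cytochromes, at -0.99 ± 0.29 and -0.79 ± 0.18, the bile acid uptake transporter SLC10A1 at -0.93 ± 0.35, and the cell cycle inhibitor CDKN1A at -0.78 ± 0.15. The 10 genes of highest level were the chaperones HSPA8 (7.45 ± 0.15) and HSPD1 (7.27 ± 0.14), alpha-fetoprotein AFP (7.44 ± 0.11), the oligosaccharyltransferase subunit DAD1 (7.40 ± 0.13), the sterol enzyme MSMO1 (7.28 ± 0.13), the lysosomal membrane protein LAPTM4A (7.23 ± 0.15), the gut and brain peptide neurotensin NTS (7.22 ± 0.15), fibrinogen beta FGB (7.20 ± 0.10), albumin ALB (7.19 ± 0.18) and the nuclear export factor CSE1L (7.19 ± 0.08). Their levels lay close together and their order depends on probe binding. With keratin-associated proteins, taste receptors and similar families as the background, 9190 of 18132 genes (50.7%) were above it.

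**Figure D1:**
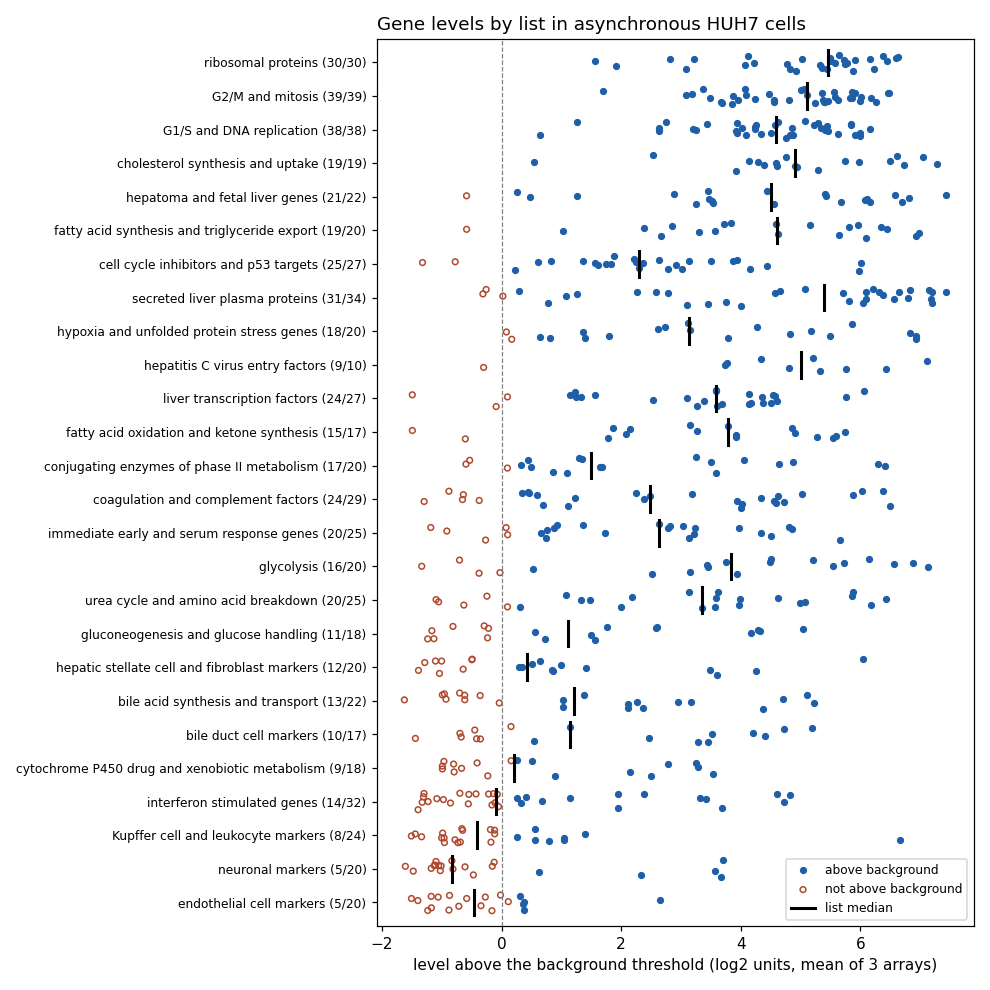
Level of each measured gene above the background threshold (x axis, log2 units, mean of 3 arrays) in the 26 gene lists (y axis, with genes above background over genes measured). Filled points were above background, open points were not, and bars mark list medians, which run from -0.82 for neuronal markers to 5.46 for ribosomal proteins.

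Most genes for secreted plasma proteins were above background. Of 34 measured, 31 (91.2%) were above background, against 65.8% of other genes (Fisher's exact test, adjusted p = 0.00346). Besides ALB, AFP and FGB, the panel members were apolipoprotein APOB at 6.65 ± 0.13, the protease inhibitor SERPINA1 at 5.71 ± 0.06 and the high-density lipoprotein component APOA1 at 2.58 ± 0.15. The exceptions were 3 inter-alpha-trypsin inhibitor heavy chains, ITIH3 at -0.31 ± 0.21, ITIH4 at -0.26 ± 0.28 and ITIH1 at 0.02 ± 0.21. Among coagulation and complement factors, 24 of 29 were above background, a share that did not pass the test against other genes (Fisher's exact test, adjusted p = 0.123). The carboxypeptidase CPB2, a regulator of clot lysis, reached 6.49 ± 0.06 and complement C5 reached 6.38 ± 0.11. Coagulation factor F9 at -1.30 ± 0.07 and the complement genes C6 (-0.88 ± 0.18), C9 (-0.65 ± 0.04), MASP2 (-0.64 ± 0.16) and C4BPB (-0.37 ± 0.24) were not above background.

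Transcription factors of the liver were above background in 24 of 27 cases (88.9%; Fisher's exact test, adjusted p = 0.0277). The pioneer factors FOXA1 and FOXA2 stood at 4.54 ± 0.15 and 4.61 ± 0.23, and their relative FOXA3 at 3.39 ± 0.22. XBP1, a regulator of secretory capacity, stood at 6.07 ± 0.19 and the nuclear receptor NR5A2 at 5.75 ± 0.09. The drug-sensing nuclear receptors NR1I3 (-1.49 ± 0.22) and NR1I2 (-0.09 ± 0.22) and the glucose-responsive factor MLXIPL (0.10 ± 0.26) were not above background. This call ended with the other families as background (adjusted p = 0.0805, Fisher's exact test) and when genes needed at least 4 probesets (adjusted p = 0.131, Fisher's exact test). Of 22 hepatoma and fetal liver genes, 21 were above background (95.5%; Fisher's exact test, adjusted p = 0.0063). They included AFP, the surface proteoglycan GPC3 at 6.69 ± 0.12, the surface glycoprotein CD24 at 6.81 ± 0.16 and the fetal growth factor IGF2 at 3.54 ± 0.18, and the exception was REG3A at -0.59 ± 0.07.

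Lipid synthesis genes were above background with few exceptions. All 19 measured genes of cholesterol synthesis and uptake passed (Fisher's exact test, adjusted p = 0.00188), with the enzymes MSMO1 at 7.28 ± 0.13 and SC5D at 7.05 ± 0.08 at the top. Of 20 genes of fatty acid synthesis and triglyceride export, 19 passed (Fisher's exact test, adjusted p = 0.00897), led by the desaturases FADS2 at 6.99 ± 0.11 and SCD at 6.94 ± 0.18, and the exception was THRSP at -0.58 ± 0.08. Fatty acid oxidation and ketone synthesis genes passed in 15 of 17 cases, with ACAA2 at 5.74 ± 0.15 and HADHA at 5.59 ± 0.17, and with ACADL at -1.49 ± 0.17 and the ketone enzyme BDH1 at -0.61 ± 0.13 not above background. That list did not pass the test (Fisher's exact test, adjusted p = 0.122), but did with the 99th percentile, the other families or a margin of 0.5 (adjusted p = 0.0222, 0.00686 and 0.0396, Fisher's exact test).

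Functions of the mature hepatocyte were split gene by gene. Among drug-metabolising cytochromes, 9 of 18 were above background (Fisher's exact test, adjusted p = 0.262), including the dioxin-inducible CYP1A1 at 3.54 ± 0.24 and CYP2J2 at 3.28 ± 0.14, while CYP4A11 stood at -0.99 ± 0.35. Conjugating enzymes were above background in 17 of 20 cases (adjusted p = 0.148, Fisher's exact test), with the glucuronosyltransferase UGT2B4 at 6.41 ± 0.10 and the glutathione transferase GSTP1 at 6.30 ± 0.22. The exceptions were UGT2B15 (-0.60 ± 0.13, from 1 probeset), NAT2 (-0.53 ± 0.10) and NNMT (0.10 ± 0.26), and with the other families as background the count was 8. UGT2B and CYP3A genes have close paralogs whose RNA can bind each other's probes. In bile acid synthesis and transport, 13 of 22 passed (adjusted p = 0.573, Fisher's exact test): the growth factor co-receptor KLB stood at 5.22 ± 0.18 and the canalicular exporter ABCC2 at 5.10 ± 0.19, against CYP7A1 (above) and the uptake transporter SLCO1B1 at -0.99 ± 0.11. Urea cycle and amino acid breakdown genes passed in 20 of 25 cases (adjusted p = 0.2, Fisher's exact test). HGD, of tyrosine breakdown, reached 6.43 ± 0.09 and the aminotransferase GOT2 6.18 ± 0.15, whereas the urea cycle enzyme OTC (-1.09 ± 0.04), SDS (-1.05 ± 0.07), HPD (-0.63 ± 0.11), PRODH (-0.24 ± 0.10) and PRODH2 (0.10 ± 0.20) were not above background.

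Of 18 genes for gluconeogenesis and glucose handling, 11 passed (7 with the other families as background), a share that did not differ detectably from other genes (Fisher's exact test, adjusted p = 0.804). Pyruvate carboxylase PC stood at 5.03 ± 0.17, the glucose-6-phosphate transporter SLC37A4 at 4.32 ± 0.18 and PCK2 at 2.60 ± 0.22. The gluconeogenic enzyme PCK1 (-1.24 ± 0.25) and the liver glycogen synthase GYS2 (-1.16 ± 0.13) were not above background. Neither were PFKFB1 (-1.13 ± 0.17), FBP2 (-0.81 ± 0.23), FBP1 (-0.29 ± 0.07), PKLR (-0.23 ± 0.07) and G6PC1 (-0.22 ± 0.03). In glycolysis, 16 of 20 passed (adjusted p = 0.284, Fisher's exact test). Lactate dehydrogenase A, LDHA, reached 7.13 ± 0.17 and the enolase ENO1 6.88 ± 0.15. The other lactate dehydrogenase subunit, LDHB, stood at -1.33 ± 0.16, hexokinase HK1 at -0.70 ± 0.09, the glucose transporter SLC2A3 at -0.38 ± 0.16 and the phosphofructokinase PFKP at -0.03 ± 0.23.

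**Figure D2:**
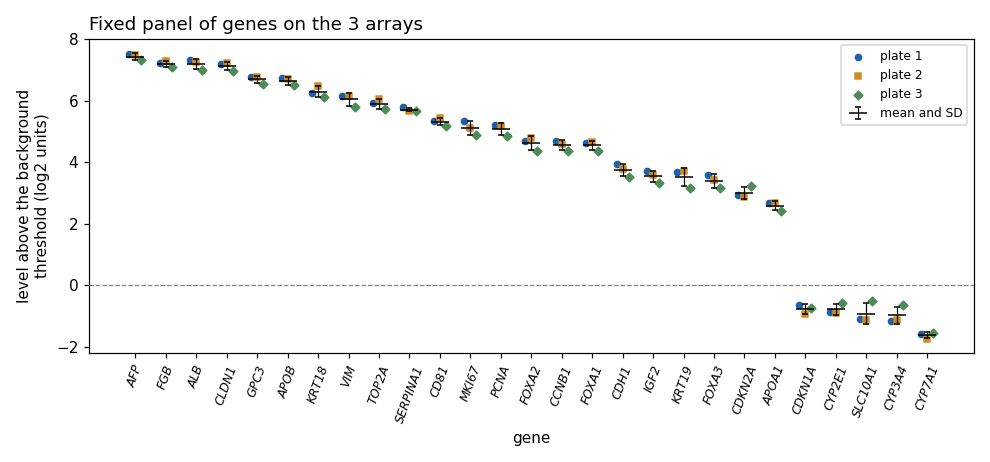
Level above the background threshold (y axis, log2 units) of the 27 measured genes of the fixed panel (x axis) on each of the 3 plates, with mean and SD. The 22 genes above background have means of 2.58 or higher and the other 5 lie below 0 on all plates.

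All 38 measured genes of the G1/S transition and DNA replication were above background (Fisher's exact test, adjusted p = 3.3e-06), as were all 39 of G2/M and mitosis (Fisher's exact test, adjusted p = 3.3e-06). The kinase CDK4 stood at 6.16 ± 0.18, the helicase subunit MCM7 at 5.99 ± 0.14 and the sliding clamp PCNA at 5.08 ± 0.20. The condensin subunits SMC4 (6.47 ± 0.10) and NCAPG (6.45 ± 0.08), topoisomerase TOP2A (5.90 ± 0.17), the proliferation marker MKI67 (5.11 ± 0.23) and cyclin CCNB1 (4.55 ± 0.17) represented the mitotic list. Among inhibitors of the cycle and p53 targets, 25 of 27 passed (Fisher's exact test, adjusted p = 0.00556). The retinoblastoma gene RB1 stood at 6.02 ± 0.13, the p53 ligase MDM2 at 5.98 ± 0.26 and CDKN2A at 3.01 ± 0.20, and the members not above background were CDKN1A and the death receptor FAS (-1.32 ± 0.09). This call ended with the other families as background (19 of 27; adjusted p = 0.0805, Fisher's exact test).

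Ribosomal protein genes, which have many processed pseudogenes that can share probes, were above background in 30 of 30 cases (Fisher's exact test, adjusted p = 5.09e-05), for example RPL5 at 6.63 ± 0.14 and RPL18 at 6.59 ± 0.14. Immediate early and serum response genes passed in 20 of 25 cases (adjusted p = 0.2, Fisher's exact test), with the matricellular gene CCN2 at 5.65 ± 0.26 and ANKRD1 at 4.85 ± 0.34, and with EGR2 (-1.18 ± 0.11), EGR3 (-0.92 ± 0.17), ATF3 (-0.27 ± 0.11), FOSB (0.08 ± 0.23) and KLF4 (0.10 ± 0.22) not above background. Hypoxia and unfolded protein stress genes passed in 18 of 20 cases (adjusted p = 0.0568, Fisher's exact test). The endoplasmic reticulum chaperones HSP90B1 and CALR stood at 6.94 ± 0.16 and 6.93 ± 0.14, and ANKRD37 (0.08 ± 0.17) and the hypoxia marker CA9 (0.17 ± 0.14) did not pass. This list did pass the test under 9 of 13 other settings, among them the mean over probesets (20 of 20; adjusted p = 0.00252, Fisher's exact test) and without array 1 (19 of 20; adjusted p = 0.00856, Fisher's exact test) or array 2 (18 of 20; adjusted p = 0.0334, Fisher's exact test).

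Interferon stimulated genes were above background less often than other genes, in 14 of 32 cases (43.8%; Fisher's exact test, adjusted p = 0.0277), and in 9 with the other families as background. The double-stranded RNA kinase EIF2AK2 stood at 4.82 ± 0.19 and MX2 at 4.72 ± 0.39. The RNA sensor TLR3 (-1.40 ± 0.13) and the antiviral gene RSAD2 (-1.33 ± 0.15) were the lowest of the 18 that did not pass. Of 10 measured entry factors of hepatitis C virus, for which this line is a common host, 9 were above background (adjusted p = 0.234, Fisher's exact test). CLDN1 stood at 7.12 ± 0.14, the transferrin receptor TFRC at 6.42 ± 0.19 and the tetraspanin CD81 at 5.32 ± 0.12, and CLDN9 at -0.30 ± 0.06 was not above background. The list, again at 9 of 10, passed the test with the other families as background (adjusted p = 0.0401, Fisher's exact test).

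Markers of other cell types were above background less often than other genes in 3 of 5 lists. Endothelial markers passed in 5 of 20 cases (Fisher's exact test, adjusted p = 0.0012), of which PECAM1 stood at 2.65 ± 0.25 and LYVE1, ENG, PLVAP and ESAM at 0.31 to 0.38, while EMCN (-1.51 ± 0.11) and FLT1 (-1.40 ± 0.12) were not above background. With the 99th percentile, the other families or a margin of 0.5 the count was 1. Neuronal markers passed in 5 of 20 cases (Fisher's exact test, adjusted p = 0.0012): the microtubule protein MAP2 at 3.71 ± 0.27, the vesicle protein SYT1 at 3.66 ± 0.25, TUBB3 at 3.56 ± 0.21, SNAP25 at 2.33 ± 0.10 and SYP at 0.63 ± 0.15, against NEFM at -1.61 ± 0.45 and ELAVL4 at -1.48 ± 0.06. Kupffer cell and leukocyte markers passed in 8 of 24 cases (Fisher's exact test, adjusted p = 0.00556). Lysozyme, LYZ, reached 6.66 ± 0.15 with 8 of 8 probesets above background, and the lysosomal CD68 1.39 ± 0.08, while the leukocyte phosphatase PTPRC (-1.44 ± 0.06) and the B cell marker MS4A1 (-1.51 ± 0.05) were not above background. Their count was 4 with the 99th percentile, 5 with a margin of 0.5 and 1 with the other families.

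Hepatic stellate cell and fibroblast markers were above background in 12 of 20 cases (adjusted p = 0.665, Fisher's exact test), with the intermediate filament VIM at 6.04 ± 0.20 and the matrix protein FBLN1 at 4.25 ± 0.17, and with POSTN (-1.39 ± 0.12) and FAP (-1.28 ± 0.32) not above background. With the 99th percentile or the other families, 6 and 4 members passed, and the share was then lower than in other genes (adjusted p = 0.0365 and 0.0141, Fisher's exact test). Bile duct markers passed in 10 of 17 cases (adjusted p = 0.662, Fisher's exact test), with ANXA4 at 5.20 ± 0.09 and SOX4 at 4.72 ± 0.12 above background and CLDN10 (-1.44 ± 0.08) and CLDN4 (-0.70 ± 0.04) not. The panel's epithelial genes KRT18, KRT19 and CDH1 stood at 6.30 ± 0.18, 3.51 ± 0.30 and 3.75 ± 0.20.

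The plates differed by a shift of the whole array and by gene. The median difference over genes was 0.34 log2 units for array 1 minus array 2, 0.19 for array 1 minus array 3 and -0.15 for array 2 minus array 3, and the SD of the differences over genes was 0.20, 0.23 and 0.23. Of the genes above background, 89 differed by over 2-fold between the highest and the lowest plate, and 21 did after the arrays were centred on their median gene. The count was 13 with the mean over probesets and 15 after quantile normalization, and 16, 26 and 51 without array 1, 2 and 3. A gene's range over 2 arrays cannot exceed its range over 3, so the counts without an array are not comparable with 89. The widest differences were in ANKRD20A20P (1.66 log2 units between plates, 1.38 after centring), SPRR4 (1.60 and 1.88), TRMT61A (1.56 and 1.15), DDX12P (1.51 and 1.62), TPTE2 (1.49 and 1.21), PDIK1L (1.40 and 1.12), the tubulin TUBA1B (1.38 and 0.97), POM121C (1.37 and 1.09), NFS1 (1.35 and 0.94) and PPAN (1.34 and 1.21). ANKRD20A20P, DDX12P, TPTE2, TUBA1B and POM121C belong to families of near-identical copies, so their values are uncertain. After centring, 8 of these 10 genes still differed by over 2-fold. Without moderation of the variance, 8 of the 10 were no longer called above background, the exceptions being TUBA1B and POM121C. The means of those 8 stayed at 0.48 (ANKRD20A20P) to 1.52 (TPTE2) above the threshold. As deposited, 0 of 26 lists moved between plates by more than matched random lists, with 0 at an unadjusted p under 0.05 (permutation of genes, lowest adjusted p = 0.874). After centring the count was also 0, with 4 lists at an unadjusted p under 0.05 (permutation of genes, lowest adjusted p = 0.269). As deposited, the range includes the shift of the whole array, so a list that moved against the shift was harder to call. With centring, the unadjusted p went from 0.984 to 0.0161 for glycolysis and from 0.066 to 0.936 for ribosomal proteins (permutation of genes). After quantile normalization no list passed, and the lowest adjusted p was 0.0793 (permutation of genes). With the mean over probesets, 2 lists moved, G2/M and mitosis and drug-metabolising cytochromes, and without array 1 fatty acid oxidation did.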

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

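All 26 lists and the count of genes above background were recomputed under 12 alternatives fixed in advance, and robust moderation and the centring of arrays were chosen after seeing the data. The count of genes above background ranged from 9190 to 12741 and never moved by over 1.5 times. Of the 338 recomputed list results, 320 kept their side of the threshold, and no list past it changed direction. The share changed direction in 2 cases not past the threshold, conjugating enzymes with the other families and bile acid genes with the 99th percentile. Liver transcription factors lost their call with the other families as background (19 of 27) and with at least 4 probesets (20 of 23), and cell cycle inhibitors with the other families (19 of 27). Calls were gained by fatty acid oxidation with the 99th percentile, the other families and the 0.5 margin (15 of 17 each), by hepatitis C virus entry factors with the other families (9 of 10), and by stellate cell markers with the 99th percentile (6 of 20) and the other families (4 of 20). Hypoxia and unfolded protein stress genes gained a call with the 90th percentile and the mean over probesets (20 of 20 each), at least 4 probesets (16 of 17), dim probesets left out and quantile normalization (19 of 20 each), the 0.5 margin (17 of 20) and no moderation (18 of 20), and the count was 18 to 19 when an array was left out, past the threshold without replicate 1 or 2. Genes over 2-fold between plates fell from 89 to 13 with the mean over probesets, 15 with quantile normalization and 21 with centring, and were 16 without replicate 1, 26 without replicate 2 and 51 without replicate 3. The counts without a replicate are not comparable with 89, since a range over 2 arrays cannot exceed that over 3. Lists that moved between plates numbered 2 with the mean over probesets (G2/M and cytochromes P450) and 0 to 1 when an array was left out (fatty acid oxidation without replicate 1). The lowest correlation of 2 arrays, 0.996, was 0.9979 with the mean over probesets and 0.9964 after quantile normalization. Single genes were traced only if named by the rule fixed in advance. Those of them that went from above to below the threshold did so with the other families as background (ANKRD20A20P -1.02, CD68 -0.11, DDX12P -0.45, LYVE1 -1.13, NFS1 -0.42, PDIK1L -0.79, PPAN -0.31, SPRR4 -0.13, TRMT61A -0.98), with the 99th percentile (ANKRD20A20P -0.26, LYVE1 -0.36, PDIK1L -0.03, TRMT61A -0.21) and with the margin (ANKRD20A20P -0.02, LYVE1 -0.12), because a higher threshold is subtracted. The cause of the other changes was not tested. Calls within about 1.5 log2 units of the threshold therefore depend on which family sets the background. No paired analysis was possible because the series has a single group.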

Other observations

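The gene lists in this part and the tests on array shifts and on single LYZ probesets were chosen after the first results were seen. The core machinery measured here was above background: 30 of 30 proteasome subunits and 29 of 29 respiratory chain subunits were above background (adjusted p = 3.21e-05 each over the 6 added lists, Fisher's exact test, against 65.7% of other genes), for example PSMA2 at 7.08 ± 0.14 and ATP5F1B at 7.17 ± 0.13 log2 units above the threshold (SD, n = 3). Circadian clock genes passed in 17 of 20 cases (adjusted p = 0.0966, Fisher's exact test), with CLOCK at 4.78 ± 0.22, PER2 at 3.33 ± 0.15 and NR1D2 at 3.94 ± 0.05, while PER3 (-0.68 ± 0.10), RORA (-1.07 ± 0.19) and CIART (-1.20 ± 0.34) did not.

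Homeobox cluster genes were above background in 15 of 36 cases, less often than other genes (41.7%; adjusted p = 0.00494, Fisher's exact test). Members above background included HOXC10 at 3.25 ± 0.09, HOXC9 at 2.74 ± 0.18 and HOXA9 at 2.33 ± 0.14, whereas HOXB5 stood at -1.60 ± 0.07 and HOXD10 at -1.74 ± 0.08. The difference between clusters was not tested. Cancer-testis antigens passed in 5 of 21 cases, less often than other genes (23.8% against 65.8%; adjusted p = 0.000204, Fisher's exact test): PRAME at 3.36 ± 0.26, MAGEB2 at 3.33 ± 0.14 from 1 probeset, MAGEA8 at 1.15 ± 0.20, CTAG2 at 0.82 ± 0.14 and DDX43 at 0.45 ± 0.30. A hypothesis that they are expressed more often than the keratin-associated, taste receptor, defensin, vomeronasal receptor and late cornified envelope families (41 of 142) was left open (Fisher's exact test, two-sided, p = 0.797).

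Neurotensin, lysozyme and SPINK1 (6.58 ± 0.17), all products of gut or pancreas, stood among the high levels. SPINK1 was also a member of the fixed list of hepatoma and fetal liver genes. A hypothesis that gut and pancreas products are expressed in this line as a group was prompted by NTS and LYZ. Of 26 measured, 9 were above background, less often than other genes (34.6% against 65.8%, Fisher's exact test, two-sided, p = 0.00141). That comparison cannot decide the hypothesis, because genes of few tissues can be called less often than genes at large. The other tissue-restricted families were called in 41 of 142 cases (28.9%), and the list was not tested against them. Most members, 17 of 26, were not above background, and INS, GCG and OLFM4 stood at -1.80 ± 0.05, -1.42 ± 0.09 and -1.13 ± 0.09.

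Lysozyme was the one leukocyte marker far above background. Leukocytes among the plated cells would bring their other abundant transcripts, but the median of PTPRC, TYROBP, FCER1G, CD74, S100A8, S100A9 and AIF1 lay at -0.205 ± 0.0689 log2 units, and of these 7 only S100A9 (1.04 ± 0.01) was above background. A single cross-hybridising probeset could not set the level of LYZ, which is a median over 8 probesets. The lowest of the 8 lay at 0.877 ± 0.142 above the probeset threshold. That outcome was already set by the count of 8 of 8 probesets given above, so it is no separate test. Beyond these technical explanations, no biological one was tested, since the design has 1 group.

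The choice of background family matters because the families differ. Late cornified envelope genes were called in 11 of 15 cases and keratin-associated protein genes in 28 of 72, against 0 of 23 taste receptors and 1 of 26 defensins. If GC content of the probes raised the signal, the GC-rich keratin-associated and cornified envelope families would lie above the AT-rich taste and vomeronasal receptors, and they did, by 0.989 ± 0.0992 log2 units. This is consistent with probe composition left in the values, and then GC-rich genes just above the threshold may be called too readily, but probe sequences were not used here and expression of these families was not excluded.

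Of the 89 genes that differed by over 2-fold between plates, 76 were highest on array 1 and 66 were lowest on array 2. A shift of equal size for all genes of an array, as the only cause, is argued against for all 89. The median difference over genes between 2 arrays was at most 0.34 log2 units, while each of these genes differed by over 1. On arrays 1, 2 and 3 the median level of olfactory receptor genes was 5.81, 5.55 and 5.83. That of the other genes was 8.69, 8.28 and 8.41, so the shift varied with level. After quantile normalization the count of genes over 2-fold was 15. How much a shift that varies with level added was not tested. After centring, 18 stayed over 2-fold. For the other 71, how much the shift added stays open, since centring by itself takes a gene just past 2-fold under it when its difference runs with the shift. Few probesets per gene is a second candidate explanation, which stays open: these genes had a median of 7 probesets against 11 for the others, below the 9 to 13 of random sets of that size but not as low as the bound fixed for the test. A difference in the state of the plates was not tested.

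Of the 22622 probesets with no listed gene, 10347 (45.7%) were above the probeset threshold on all 3 arrays, against 65.2% of those with 1 gene.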
